A study of Zea mays
Mycosarcoma maydis with 8 samples.

How the data were processed

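Total RNA from pools of maize anthers was measured on 4 two-colour Agilent arrays that carry probes for maize and for the smut fungus Ustilago maydis. Each array held 1 sample from tassels injected with the fungus and 1 from mock-injected tassels, collected 3 days after injection. The infected sample carried Cy3 on arrays 1 and 2 and Cy5 on arrays 3 and 4. Per the labels' protocols, about 50 anthers were pooled per sample and 500 ng of RNA was amplified and labelled.

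Per the file headers, the spots were read with Agilent Feature Extraction 10.5.1.1, and the submitters' processing notes name the same software. The authors deposited scanner files with the intensity of every spot in both channels, its local background and quality flags, and a table of normalized intensity values. Each of its columns had a median of 40.9 over all probes, so they had been brought to a common level. The method that did so was not given in the sources used here, and the table served only as an alternative. The scanner's flags are 0 or 1 for each spot and channel, per the file headers. Of 45220 spots, 43803 were not controls, and they held 43592 different probes.

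Groups were taken from the source names, which end in a different letter for each of the channels of an array. The titles and tissue labels of the 4 Cy5 samples name the opposite group from their source names. Titles would put both channels of an array in 1 group, against the array descriptions, which set infected against mock anthers. Grouping by titles and the Cy3 samples alone, for which the labels do not conflict, were therefore run as alternatives. Replicate numbers name samples. Whether they pair samples was checked, and the result is given with the alternatives. The labels do not state that samples came from separate plants, so p-values measure the spread between these samples, which may be technical.

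Intensity was corrected with normexp at an offset of 50, which shrinks the ratios of dim probes, and normalized by loess within each array with control spots and fungal probes at weight 0. Spots with outlier flags were left out and spots of a probe averaged. Probes well above background in at least 3 of the 4 samples of either group were tested, 33598 for maize and 3700 for the fungus. The log2 ratio of infected over mock was fitted with limma 3.58.1 in R 4.3.3 with a term for the dye, and p-values were adjusted by the Benjamini-Hochberg method at 0.05 within each organism. Gene lists were tested with fry and camera.

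The fungal signal of the samples labelled infected replicate 1 and mock replicate 4 went against their labels, and no sample was regrouped. A second fit was chosen after the fungal signal had been seen. It used the channels separately after Aquantile scaling, with dye as a term and array as a random block, and left out the sample labelled infected replicate 1. The block's correlation was estimated from all tested probes. Estimates from 2 subsets of 3000 probes were run first and gave other counts, so the subsets were set aside. The scaling still used the array of the sample left out.

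Maize identifiers were looked up in a RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0. Of 36398 identifiers, 30 matched, and 23 of 24 maize gene lists had no member, so tests of maize lists are void. No column used here states the organism of a probe. Probes with identifiers that begin with um were taken as fungal and all others as maize, and what is said of either organism rests on that. The files do not pair the um identifiers with gene names, so fungal genes are given by identifier. The lists of um numbers were drawn from general knowledge of the fungus before the data were examined, and a list of fungal ribosomal proteins had no member. The groups, the 4-array fit and the rule for named genes were fixed at the same time. That rule took every member of 3 fungal lists, and maize genes with a name, an adjusted p under 0.05 and the same direction on all 4 arrays. No maize gene met it. Maize genes named by the files, and the maize identifiers given below, were chosen after their values were seen.

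The fits were tested on simulated data with 100 probes changed by log2 1 and 100 by log2 2. With spreads drawn from limma's fitted prior, the 4-array fit recovered 0 of 100 maize probes at either size and made 0 false calls, and it recovered 92 of 100 fungal probes at log2 2 and 69 of 100 at log2 1. With the moderated spread of each probe, it recovered 79 of 100 maize probes at log2 2. The 7-sample fit recovered 91 of 100 maize probes at log2 1, but 9.05% of its calls were false, and 12.6% with the moderated spread, above the 5% aimed at. It overestimated the array correlation, at 0.659 where 0.561 had been simulated. The ratio fit on arrays 2 to 4 alone recovered 88 of 100 maize probes at log2 1 and 99 at log2 2 with the prior spread. The number of arrays therefore does not account for the 0 recovered with 4 arrays. The SD of maize log2 ratios was 1.10 on array 1, against 0.37 to 0.54 on the other arrays.

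The alternatives covered the dye term, the background correction and its offset, the loess probes or median centring, the filter on dim probes, outlier spots, a threshold of 2-fold, the empirical Bayes options, separate channels, the grouping labels, the deposited table and leaving out each array. A probe not well above background in any sample of a group has a bound in place of a fold. Bounds were computed from separate channels after loess and Aquantile, against the lowest signal among probes well above background or the probe's own signal, whichever was higher.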

Results

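Anthers of 0.3 to 0.6 mm were compared 3 days after tassels were injected with the smut fungus Ustilago maydis or mock-injected, with 4 samples in each group. The comparison asked which maize and fungal transcripts differed between infected and mock anthers. The median background-subtracted brightness of maize probes ranged from 15.7 in mock replicate 2 to 93.5 in the sample labelled infected replicate 1. Between 81.1% and 96.1% of 36818 maize probes were well above background in a sample, and the groups' shares did not differ beyond the spread between samples (exact permutation test, two-sided p = 0.629, n = 4 per group; within arrays, exact sign-flip p = 0.625).

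On each of the 4 arrays, a larger share of fungal probes was detected in the infected than in the mock sample. On average 59.2% ± 6.62 (SD, n = 4) of 6774 fungal probes were well above background in infected samples and 35.3% ± 6.90 (SD, n = 4) in mock samples. Every infected sample lay above every mock sample (exact permutation test, two-sided p = 0.0286, n = 4 per group). That test treats the 8 samples as independent, although each array held 1 of each group. Within arrays infected exceeded mock by 23.9 ± 7.39 percentage points (SD, n = 4), and the exact sign-flip permutation test, added after the data were seen, gave p = 0.125, the smallest that 4 arrays allow. With 4 arrays that test cannot pass at 0.05 whatever the data, so it neither supports nor removes the difference. Each of these tests counts the sample labelled infected replicate 1 as infected, at 54.9%. Yet 31 fungal markers lay there at a median of 1.55% of their level in the other infected samples. The markers were chosen from these data as bright in those samples and not detected in mock replicates 1 and 2. Without the sample labelled infected replicate 1 the shares were 60.6% ± 7.31 (SD, n = 3) and 35.3% ± 6.90 (SD, n = 4). The exact permutation test then gave p = 0.0286, the smallest it can give, again with samples taken as independent. Without the sample labelled mock replicate 4 as well, the exact p was 0.1, the smallest that 3 samples against 3 allow. In mock samples the share went with the median brightness of maize probes. Mock replicates 3 and 4, with 83.7 and 70.9, had shares of 41.9% and 40.3%. Mock replicates 1 and 2, with 21.7 and 15.7, had 32.0% and 27.3%. Among infected samples the brightest, labelled replicate 1, had the lowest share. Whether the share depends on signal strength was not tested. Fungal probes were dim, with a median background-subtracted brightness of 2.33 to 5.10 in infected samples and 0.26 to 1.19 in mock samples. The 95th percentile of negative controls was 0.11 to 0.92, so many detected fungal probes lay near the floor. In at least 3 samples of the group, 3594 fungal probes were detected in infected anthers and 1588 in mock anthers. Of these, 1343 were detected in at least 3 infected but at most 1 mock sample, and 34 in at least 3 mock but at most 1 infected sample.

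**Figure D1:**
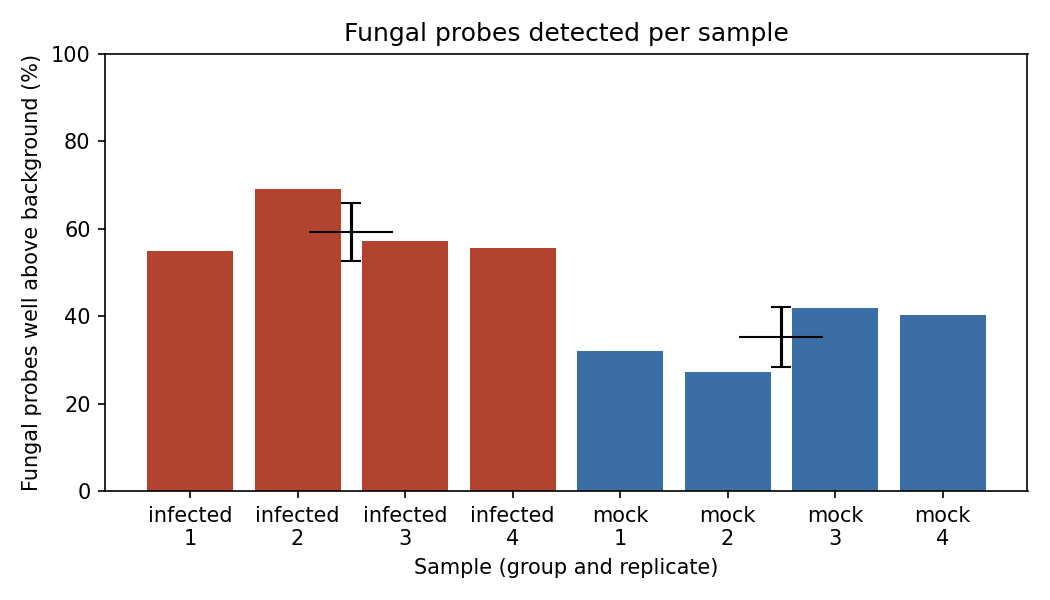
Share of 6774 fungal probes well above background in each sample, in percent; bars are samples, black marks are the group mean and SD (n = 4). The infected samples lie between 54.9% and 69.0% and the mock samples between 27.3% and 41.9%.

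On the fungal effector list, secreted proteins that act on the plant, 6 of 9 probes had a brightness of 66.0 or more in each of infected replicates 2, 3 and 4. The other members, um02239, um05302 and um10072, were dim there, at 22.1 or less. Infected replicates 3 and 4 carry mock in their titles, as do their Cy3 partners, mock replicates 1 and 2. In those partners the 6 probes had 31.3 or less, and the dim members were lower as well. These values argue against the titles of infected replicates 3 and 4, and go with their source names. On arrays 1 and 2 both samples are titled infected, and the list does not settle those titles. The probe for um03223 had a background-subtracted brightness of 2634, 1610 and 1511 in infected replicates 2, 3 and 4, against 12.8, 10.6 and 6.1 in mock replicates 1, 2 and 3. In the sample labelled infected replicate 1 it was 8.6, and in the sample labelled mock replicate 4 it was 227.9. The probe for um01987 had 322.6, 149.9 and 71.5 in infected replicates 2, 3 and 4. In the sample labelled infected replicate 1 it was 0.0. There um02475 had 36.5, above its 2.4 to 19.8 in mock samples, and um01375 had 119.6, close to the 120.5 of its partner on array 1. For most of the list, the fungal signal of these samples went against their labels, and every direction below that uses them carries that doubt.

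**Figure D2:**
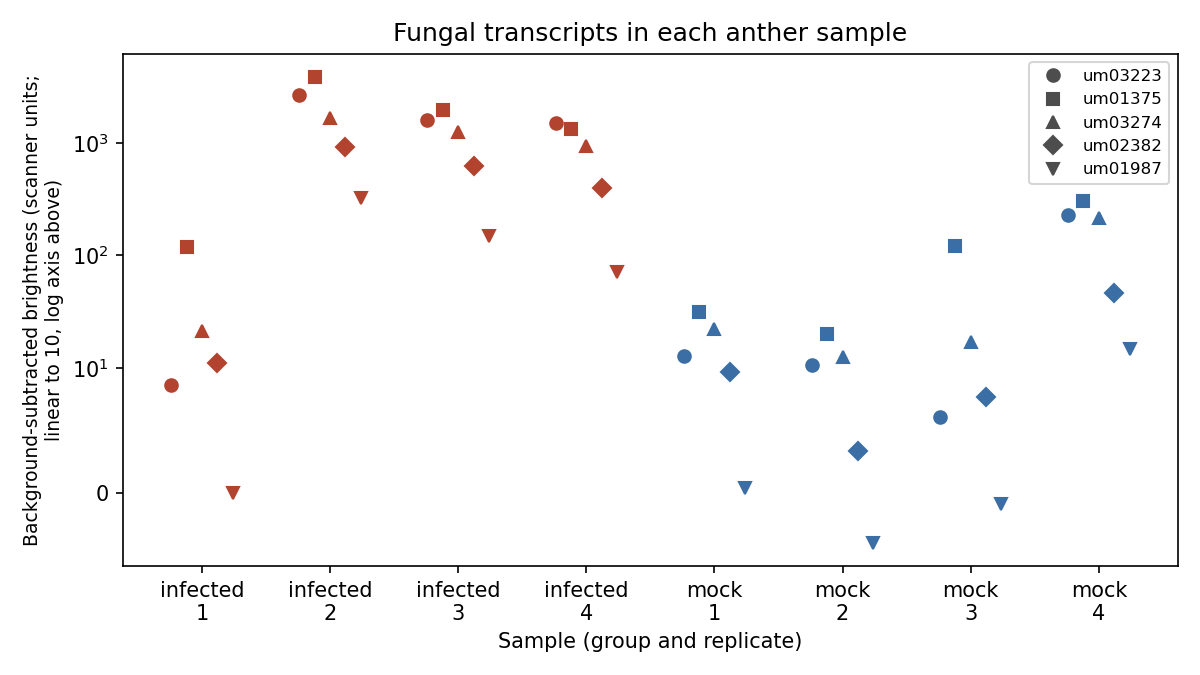
Background-subtracted brightness of 5 fungal probes in each sample, in scanner units on an axis that is linear to 10 and logarithmic above; points are single samples. For um03223 the values are 2634, 1610 and 1511 in infected replicates 2, 3 and 4 and 8.6 in the sample labelled infected replicate 1.

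Across all fungal probes, the within-array median log2 ratio of infected over mock was close to 0 on 3 of 4 arrays. It was 0.01 on array 1, 0.17 on array 2, 0.01 on array 3 and 0.03 on array 4, with a mean of 0.06 ± 0.08 (SD, n = 4). The exact sign-flip permutation test gave a two-sided p = 0.125 (n = 4), the smallest that 4 arrays allow. With scanner-processed signals the direction flipped on arrays 1, 3 and 4, where the medians were -0.17, -0.26 and -0.29, against 0.99 on array 2. Without array 2 the mean was 0.017, so this value does not settle which channel held the infected sample.

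With all 4 arrays, the effector list had the highest ratios among the fungal lists, but no fungal probe passed the planned test. The log2 ratio was 2.62 ± 0.91 (SE, n = 4) for um01375, 2.59 ± 0.87 for um03223 and 2.23 ± 0.73 for um03274, each with an adjusted p of 0.525 in limma. On array 1, which holds the sample labelled infected replicate 1, the log2 ratios of these probes were -0.01, -0.00 and 0.12. Without array 2 the values were 1.42 for um01375, 1.48 for um03223 and 1.28 for um03274. Without array 1, which removes the sample labelled infected replicate 1, they were 3.82, 3.71 and 3.17, each with an adjusted p of 0.0191 in limma. Of 3700 fungal probes limma called 0, and 45 had an unadjusted p under 0.05, where 185 are expected by chance. Limma's intraspot-correlation fit also called 0, with 253 at an unadjusted p under 0.05. Median centring in place of loess called 235, of which 233 were higher, with um03223 at 2.84 and um01375 at 2.85. Its adjusted p of 3.0e-27 in limma for um01375 is too small to rest on that probe's own spread over 4 arrays.

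Of the 9 members of the effector list, 8 rose in infected anthers in the 7-sample fit, which was chosen after the fungal signal had been seen and leaves out the sample labelled infected replicate 1. The log2 ratio in that fit was 3.88 ± 0.25 (SE) for um03223, 3.83 ± 0.23 for um01375 and 3.33 ± 0.22 for um03274, and um05302 did not pass, at 0.07 ± 0.04 with an adjusted p of 0.178. Scanner-processed signals of the same samples gave larger log2 ratios, 6.00 for um03223, 4.97 for um01375 and 5.04 for um03274. Of 13 tested members of gene cluster 19A, a cluster of genes for secreted proteins, 11 rose, among them um05318 by 1.80 ± 0.16 and um05314 by 1.54 ± 0.15. Of 7 members of the list of mating type and filament regulators, 3 rose, with um02382 at 3.01 ± 0.16. The same numbers of members, 8, 11 and 3, passed when adjusted over the list alone. Over all 3700 tested fungal probes, 1987 passed, or 53.7%, with 1982 higher and 5 lower. The share of the regulators, 3 of 7, lay below that, and the counts of the lists were not tested against it. The sample labelled infected replicate 1 was left out for its low fungal signal, so these counts are not independent evidence. When the sample labelled mock replicate 4 was left out instead, 2 fungal probes passed.

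In the planned 4-array fit, 0 members of these lists passed in limma over all fungal probes, and 0 when adjusted over the list alone. The smallest unadjusted p in that fit was 0.0457, for um03274. With median centring in place of loess, list members did pass with 4 arrays, among them um01375, um03223, um03274, um02382, um01987 and um02475. The adjusted p in limma was 3.0e-27 for um01375, although its log2 ratios with loess ran from -0.01 to 4.80 between arrays. So small a p from 4 arrays cannot rest on the probe's own spread, so these calls carry little weight. The 4-array fry test gave an adjusted p of 0.279 for each list, and 0.282 for change in either direction. Without array 1, which also removes the sample labelled infected replicate 1, fry gave 0.083 for each list. Camera with a preset correlation called the effector list at an adjusted p of 0.0165, with an adjusted p = 0.753 with an estimated correlation. In no mock sample were um05306 and um05311 well above background, while 3 of 4 infected samples measured them. From the mean of all 4 infected samples they were at least 1.45-fold and at least 1.37-fold higher, with an adjusted p of 0.525 for both in the 4-array fit. Detection was the same for um05305, um05317, um10072, um00578 and um03172, with smaller bounds, from 1.04-fold to 1.23-fold.

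For maize, log2 ratios of infected over mock went together between arrays, but no probe passed the planned test. They correlated across maize probes at r = 0.89 between arrays 3 and 4 and between 0.40 and 0.52 for the other pairs of arrays. Arrays 3 and 4 both held the infected sample in Cy5, and these ratios keep any dye effect, which can add to their agreement. Arrays 1 and 2, which also share their dyes, correlated at 0.40. Genes are not independent replicates, so these values carry no p. Limma called 0 of 33598 maize probes with 4 arrays, and 5015 had an unadjusted p under 0.05, where 1680 are expected by chance. The smallest adjusted p was 0.144, limma's intraspot-correlation fit called 1403, and scanner-processed signals gave 1234, 830 higher and 404 lower. Without array 1 the count was 4332, and without array 2 it was 15153.

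The probe for TC292792 was far brighter in infected anthers on each array. Its log2 ratios were 8.21, 5.30, 6.98 and 6.70 on arrays 1 to 4, and the 4-array value was 6.80 ± 0.56 (SE, n = 4) with an adjusted p of 0.148 in limma. The probe for AW497968 had -2.98, -3.93 and -3.98 on arrays 2 to 4 and was also below 0 on array 1, with a 4-array value of -2.97 ± 0.38 and an adjusted p of 0.201. For TC289637 the log2 ratio was 0.94 on array 1 and -4.26, -3.02 and -3.64 on arrays 2 to 4. In the 7-sample fit TC292792 rose by 5.90 ± 0.26 (adjusted p = 0.000351), AW497968 fell by 3.55 ± 0.27 (adjusted p = 0.00132) and TC289637 fell by 3.69 ± 0.63 (adjusted p = 0.0154). The files do not pair these identifiers with gene names, and they were chosen after their values were seen.

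In the 7-sample fit, 4200 maize probes passed, 2668 higher and 1532 lower in infected anthers. The median log2 ratio was 0.76 among those higher and -0.59 among those lower, and 906 rose and 179 fell by more than 2-fold. Scanner-processed signals of the same samples turned the balance, with 4447 higher and 6885 lower. The count was 1151 without the array block, and 13731 when the sample labelled mock replicate 4 was left out instead. With simulated data, 9.05% or 12.6% of the calls of this fit were false. Among the other splits of these 7 samples the highest count was 5444, against 4277 for the real split in the same run. It came from the split that counts mock replicate 1 with the infected samples and leaves the others as labelled, and the next highest count was 29.

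Maize genes that the files name gave 0 calls with 4 arrays. AM1, which is needed for entry into meiosis and was the only member of the meiosis list, had a log2 ratio of -0.15 ± 0.11 (SE, n = 4) with an adjusted p of 0.554 in limma. ZmSMC1, a cohesin subunit, had -0.37 ± 0.12 with an adjusted p of 0.324 and was lower on 4 of 4 arrays. It had -0.78 on array 1 and -0.19 to -0.27 on the others. ZMATP70 had 0.50 ± 0.17 with an adjusted p of 0.338, from -0.47 on array 1 to 1.22 on array 4. In the 7-sample fit ZMATP70 rose by 0.78 ± 0.16 (adjusted p = 0.0303), and of the probes for the transposon MUDR 1 rose, by 0.57 ± 0.13 (adjusted p = 0.0366). AM1 did not pass in that fit, at -0.23 ± 0.07 with an adjusted p of 0.0731, nor did ZmSMC1, at -0.22 ± 0.06 with 0.0645.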

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

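The tests of single samples, of fungal RNA in mock samples and of the scanner's flag in this part were chosen after the result was seen, while those of cross-hybridisation and of the splits were set before. The 7 samples, and the arrays used for cross-hybridisation, were themselves chosen after the fungal signal had been seen. Of 77 groups of 4 values, 6 had a value far from the other values of its group, where chance gives about 1 in 20.

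Infected replicate 2 had 69.0% of fungal probes above background, far from the other infected samples. Array 2 had a median fungal log2 ratio of 0.17, far from the other arrays. The log2 ratio of a MUDR probe was -0.26 on array 2. On array 1 the log2 ratios were -0.69 for ZmSGO1, -0.78 for ZmSMC1 and -1.09 for ZmSMC3, each far from the other arrays.

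The sample labelled infected replicate 1 had 31 fungal markers at a median of 1.55% of their level in infected replicates 2 to 4. These markers were chosen as bright in each of infected replicates 2 to 4 and not detected in mock replicates 1 and 2. That choice sets a high level for comparison, while the sample itself played no part in it. An exchange of the channels of array 1 is argued against by its mock partner, where the markers had a median of 1.05%, and a fault of the array by 10 spike-ins, with log ratios that correlated with those of the other arrays at 0.977 or more. Some maize values run against a mock sample under an infected label. The sample's maize signal correlated at 0.83 to 0.85 with the other infected samples and 0.72 to 0.79 with the mock samples. Such correlations do not sort every sample by group. Mock replicate 1 correlated at 0.95 to 0.96 with infected replicates 2 to 4 and at 0.95 to 0.98 with the other mock samples. Over 4332 maize probes called from the other arrays, the sample labelled infected replicate 1 lay a median log2 of 0.76 to 1.13 from the mock samples. The mock samples lay up to 0.40 from each other. Over the same probes, the median log2 ratio on array 1 was 1.24 for those called higher and -0.997 for those called lower. On arrays 2 to 4 these medians were 0.76 and -0.59. A mock sample under an infected label stays open because all contrasts of this sample were wide. Relative to their own SD the shifts from the mock samples were 0.80 to 1.15, against up to 0.99 between mock samples. That SD was taken over all maize probes, so a response to infection would widen it too, and the ratio cannot decide. Of the probes, 78.0% had the same sign on array 1. This lay above the 75.3% reached between mock samples by less than the spread of those values, a condition added after the value was seen. A pool that the fungus had not reached was not tested.

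The sample labelled mock replicate 4 held fungal signal, at a median of 6.62% of infected replicate 2, its partner on array 2, over 43 markers. Over the other set of 31 markers, it lay at a median of 6.03% of the level in infected replicates 2 to 4. The choice of markers bears on both figures. A fixed share of the partner's signal may be the source of this signal and cannot be told apart from fungus in that pool. The 43 markers varied 1.66 times as much as between infected samples of opposite dye. The bootstrap interval, from 1.21 to 2.24, does not settle the matter. A first form of this test, over 7 markers and against samples of the same dye, gave 6.35, which argued against a fixed share, and was replaced after that value was seen because dye effects add to the spread. No biological explanation was tested.

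Between 27.3% and 41.9% of fungal probes were above background in mock samples. A lenient detection threshold is argued against by negative controls, of which at most 2.61% passed in a mock sample. For effector transcripts alone, fungal RNA carried into mock replicates 1 to 3 is argued against by the list's median, 2.42% of its infected level. Yet um05302 at 64.3% and um02239 at 11.9%, both dim, lay above the 10% that had been set for the median. Also dim, um10072 lay at -16.8%. Other fungal transcripts were not covered by this test. Cross-hybridisation of maize RNA could contribute. On scanner-processed signals of arrays 2 to 4, the 891 probes detected in every mock sample had a median log2 ratio of 0.39. This lay within the range that had been set for it, although 31.6% of these probes were over 2-fold higher in infected anthers. Cross-hybridisation is left open because the quartiles of these probes, -0.13 and 1.42, spread beyond that range, a condition added after the value was seen.

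Other splits of the samples bear on the counts. They used separate channels and a correlation estimated from 3000 probes, so their real counts differ from those of the other fits, and in each case 1 split that coincided with the dyes could not be fitted. For maize, 2 of 34 splits of the 7 samples called as many probes as the real one, 4277, and the highest other called 5444, so chance cannot be excluded by this count. That split differs from the real one only in mock replicate 1, which it counts with the infected samples, and the next highest called 29. Splits that moved mock replicate 2, 3 or 4 in the same way called 0, 1 and 3. Sharing most of the real contrast therefore does not by itself account for the 5444. Over the 4332 maize probes called from arrays 2 to 4, mock replicate 1 differed from the other mock samples in the direction of the calls. The median log2 was 0.20 to 0.40. With all 8 samples, 2 of 34 splits called as many maize probes as the real one, 782, and chance cannot be excluded. The highest other called 9592, several times the real count. It exchanged the samples of array 2, which sets array 1 against the other arrays, and points to a structure of the samples. For fungal probes, 1 of 34 splits of the 7 samples, the real one, called 1991, and the highest other called 394, but the 7 samples were chosen by their fungal signal, so this says nothing about chance. With 8 samples the real count was 0, which 34 of 34 splits reach whatever the data, and the highest other was 2142, so that test decides nothing either.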

How the results depend on the processing

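The tests on 7 or 6 samples, detection included, without array 1 and the dye term, and with an offset of 5 were chosen after the data were seen. The 4-array count of 0 maize probes rose to 1234 with scanner-processed signals, 1403 with the intraspot correlation, 243 with separate channels and no block, and 1686 with the series table. The replicate block lowered the count with separate channels from 243 to 194, so the move from 0 goes with the separate channels and not the block. The numbers do not pair samples (correlations of deviations -0.00, 0.05, 0.02 and -0.24), and the fungal count stayed 0. Leaving out an array in turn gave 0 to 15153 maize and 0 to 1539 fungal probes. Without array 1 there were 4332 and 1539, and without array 2 there were 15153 and 0. With the dye term, such a fit takes the spread from a pair of arrays and assumes the lone array varies alike, and without array 1 and the dye term 273 maize and 0 fungal probes were called. With simulated data, 21.6% of the maize and 13.8% of the fungal calls of the fit without array 1 were false with the moderated spread, and 7.43% and 3.00% with the prior spread. Median centring called 235 fungal probes.

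Without the sample labelled infected replicate 1, 4200 maize and 1987 fungal probes were called. Scanner-processed signals gave 11332 and 2341, no block gave 1151 and 1626, and the correlation from 3000 evenly spaced or the first 3000 probes gave 4277 and 1991 or 2905 and 1969. Leaving out the sample labelled mock replicate 4 instead gave 13731 and 2, and leaving out both gave 1602 and 1336. The cause was not tested. The lists passed fry with 7 samples, at adjusted p of 0.00023 for effectors and for regulators and 0.000802 for cluster 19A. Fry asks whether members change, not whether they change more than other probes. In that fit 53.7% of all tested fungal probes passed, and its samples were chosen by their fungal signal. These p-values therefore do not set the lists apart from other fungal probes. Without array 1, which also removes the sample labelled infected replicate 1, fry in the planned fit gave an adjusted p of 0.083 for each list, so none passed. With 4 arrays, camera with a preset correlation called effectors at 0.0165, lost with an estimated correlation, at an adjusted p = 0.753 for each list.

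The difference in the share of fungal probes detected passed with samples taken as independent (exact permutation p = 0.0286). Within arrays, a test added after the data were seen gave the smallest p that 4 arrays allow (exact sign-flip p = 0.125) and decides nothing. Detection in all 4 samples counted 2220 fungal probes in infected and 891 in mock anthers, while detection in at least 2 samples counted 4566 and 2705. Leaving out an array, with detection in at least 2 of the 3 samples left in place of 3 of 4, gave 3821 to 4267 in infected and 1941 to 2387 in mock anthers, so these counts changed in rule as well as in samples. Grouping by titles turned um03274 to -1.11, um01375 to -0.71, um03223 to -1.26, um02239 to -0.25, um01987 to -0.41, um05731 to -0.19, um02382 to -1.07, um02475 to -0.69 and um10072 to -0.036, and called 0 probes of either organism. The Cy3 samples alone turned um02239 to -0.021, and leaving out each array gave -0.012 (without array 2) to 0.22 for um10072. The mean fungal log2 ratio, 0.06, ranged from 0.017 without array 2 to 0.083 with no background correction, within its SD of 0.08, and scanner-processed signals gave 0.068 with 3 of 4 arrays below 0. Signal over background let 54.6% of fungal and 91.3% of maize probes be tested. The mean of all probes of a gene was not run, since each fungal gene had 1 probe.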

Other observations

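Of 6774 fungal probes, 589 were well above background in at least 3 infected and no mock samples, 828 in all 8 samples and 834 in no sample. For maize, 317 probes were well above background in at least 3 infected but at most 1 mock sample, and 216 in at least 3 mock but at most 1 infected sample.

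Fungal genes with neighbouring numbers may respond alike. This test was set before its result was seen, but it uses the 7-sample fit, which was chosen after the fungal signal had been seen. Over 1596 pairs of successive um numbers outside cluster 19A, the log2 values of the 7-sample fit correlated at r = 0.14 across genes, above the 95th percentile of shuffled orders, 0.04. The permutation test gave p = 0.0001, the smallest that 10000 shuffles can give. Whether successive numbers lie side by side in the genome was not tested, and genes are not independent replicates.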
